A study of Mus musculus with 3 samples.

How the data were processed

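Polyadenylated RNA of mouse embryonic stem (ES) cells was measured by RNA-seq in 3 libraries. Per the labels' protocols, RNA was taken up in TRIzol, selected with oligo(dT) and made into strand-specific libraries. The cells carried a transgene under doxycycline control (1 µg/ml) that encodes the histone variant H2A.Z fused to yellow fluorescent protein (YFP), either wild type or with the C-terminal lysines 119, 120 and 123 replaced by arginine (K3R3). YFP-positive cells were sorted, and a hairpin against the 3′ untranslated region of the endogenous H2A.Z transcript was present in both kinds of line. Wild type had 2 libraries and K3R3 had 1. The labels do not say whether the wild-type libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

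The authors deposited 1 table with a row per gene. Read counts per gene were deposited by the authors as whole numbers, made with HTSeq 0.5.4p1 on genome build mm9, per the submitters' processing notes. The aligner, the gene annotation and the strand setting of the counting were not given in the sources used here. The table held 15311 genes and its smallest count was 1 in each library, so a gene with a count of 0 in any library was not among its rows. RPKM values were deposited by the authors beside the counts. They divide each count by gene length and by 1 total per library, and that total was recovered from the counts, lengths and RPKM values with a relative deviation of at most 3.16e-07 within a column. The deposited fold ratio, its log2 and an unadjusted p-value come from the authors' own comparison, for which the submitters' processing notes name DESeq 1.10.1. Per the file headers the deposited fold and log2 columns set K3R3 against wild type. By the values they are the normalised wild-type mean divided by K3R3, with a largest relative deviation of 1.63e-08. If the count columns are named correctly, a positive deposited log2 value means higher expression in wild type, and among 1300 genes with a fitted change above 2-fold the deposited sign was opposite to K3R3 minus wild type in 100%. Every direction given here was computed from the counts and depends on the names of the count columns, which H2afz does not check. Of the other deposited columns, gene length was used for 1 correction. The class code of each gene (active or bivalent, the latter meaning promoters that carry both an activating and a Polycomb mark) came, per the file headers, from an earlier study. The header explains the codes for active and bivalent alone, and genes with other codes or none were kept apart.

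Counts were analysed with edgeR 4.0.16 in R 4.3.3. Library sizes were the column totals scaled by TMM factors, and 13829 genes with a mean of at least 0.5 CPM (counts scaled to library size) over the 3 libraries were tested. K3R3 was compared with wild type by edgeR's two-sided quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The spread came from the 2 wild-type libraries (1 residual degree of freedom), and the lone K3R3 library is assumed to vary like the wild type. The estimated prior degrees of freedom were infinite, so p-values rested on the trend of dispersion with expression and not on each gene's own spread. A second rule used no test. It counted genes whose CPM in K3R3, after adding 1, lay at least 2-fold above or below each wild-type library, among genes with a mean CPM of at least 1. As background, both counts were repeated with each wild-type library in the place of the lone library. Levels are TMM-normalised CPM, given for wild type as mean ± SD (n = 2) and for K3R3 as the value of the lone library. Fold changes are fitted log2 values with standard errors (SE). Log2 values against 1 replicate alone, without a wild-type replicate or between the replicates are no fit. They are differences of log2 CPM with a prior count of 1. That prior pulls differences of genes with few counts towards 0, so both can be smaller than the fitted value. For genes with 1 to 3 counts in a wild-type library, the ratio of K3R3 to the pooled wild type is given with its exact conditional 95% interval, which covers counting error only.

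The series design compares K3R3 with wild-type H2A.Z. Before the data were examined, the test, its alternatives, 32 gene lists and the rule for named genes were fixed. The lists covered core and naive pluripotency, primed pluripotency, neural ectoderm, mesoderm, endoderm, trophoblast, Hox genes, Polycomb target developmental regulators, Polycomb subunits, H2A.Z exchange complexes, BET bromodomain proteins, MLL/COMPASS with H3K27 demethylases, fibroblast (feeder) markers, genes of the 2-cell-like state, germline, imprinted and Y-linked genes, interferon response, p53 targets, unfolded protein response, glycolysis with hypoxia, cholesterol synthesis, Wnt, Nodal/BMP and ERK targets, histones, S phase, mitosis, ribosomal proteins, mitochondrially encoded genes, metallothioneins and cell adhesion. No mitochondrially encoded gene was among the rows of the table, so 31 lists were measured. A list was described by its calls over all genes, its calls adjusted over the list alone, and its median log2 fold change with the percentile of that median among 10000 random lists of equal size drawn from the same 20 expression bins. With 1 K3R3 library this percentile describes these libraries and is no test. The same percentile was computed for wild-type replicate 2 against replicate 1. Named genes were H2afz, H2afv and Brd2, then the 12 largest rises and the 12 largest falls among called genes with a mean CPM of at least 1 that were also at least 2-fold from both wild-type libraries, and up to 4 members of each list, called members first and then by size of change. Some genes that meet this rule are not reported here. Other genes named in the text were chosen after their values were seen, and the comparison of bivalent with active genes was added after the class column was seen.

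The other settings tried were DESeq2 size factors, no low-count filter, a minimum mean CPM of 2, DESeq2 1.42.0 with its Wald test, edgeR's likelihood ratio test, the mean in place of the median of a list, thresholds of 1.5-fold and 4-fold, and leaving out each wild-type library. Library totals implied by the deposited RPKM values, and a correction of fold changes for expression, gene length and GC content, were added after the data were seen. GC content and chromosome were taken by gene symbol from GRCm38.p6 and covered 99.7% of bivalent and 99.3% of active genes. Because the table is on mm9, no coordinates are given. The method was tested on simulated counts of the same design with 13639 genes, 200 of them changed. It called 96% of genes raised 4-fold and 83.7% of genes lowered 4-fold, against 38% of genes raised 2-fold and 28% of genes lowered 2-fold. Among 13440 unchanged genes 13 were called. The correct calls were 41 and 48 genes lowered and raised 4-fold, and 14 and 19 genes lowered and raised 2-fold. False calls were thus a larger share of all calls than the Benjamini-Hochberg threshold aims at. With no changed gene 0 of 13645 were called by edgeR's quasi-likelihood test. With unchanged genes set at a true fold of 1, the simulation does not measure calls caused by a difference between single cultures.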

Results

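Transcript levels were measured in mouse ES cells whose H2A.Z was supplied by a YFP-tagged transgene. H2A.Z is a histone variant found at promoters, including those held silent but poised in ES cells. The series asks, by its title, how mono-ubiquitylation of this histone and the bromodomain protein BRD2 bear on poised chromatin, and the K3R3 form lacks the C-terminal lysines that can carry ubiquitin. The table held 21614693 and 25426228 counts for the wild-type replicates and 24718223 for K3R3. These were 66.2%, 66.9% and 67.1% of the totals implied by the deposited RPKM values. The wild-type replicates differed by more than counting noise (24.3 per degree of freedom in a chi-square over genes), so they were kept as separate samples. K3R3 gave 30.2 against replicate 1 and 21.0 against replicate 2, so by this measure, which abundant genes dominate, it was no farther from replicate 2 than the replicates were from each other. The SD of the log2 difference over genes was 0.53 within the wild-type pair and 0.71 and 0.60 between K3R3 and its members. K3R3 had no replicate.

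The targeted gene was examined first. H2afz, which encodes H2A.Z.1, stood at 225 ± 8.89 CPM in wild type and 222 CPM in K3R3, a log2 difference of -0.02 (SE 0.19; adjusted p = 1.00 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The hairpin was present in both groups and the transgene adds coding reads, so this value checks neither the knockdown nor the label. H2afv, the gene of the paralogous H2A.Z.2, stood at 34.1 ± 4.19 CPM in wild type and 30.0 CPM in K3R3 (log2 -0.19), below both wild-type libraries. Brd2 stood at 542 ± 54.6 against 520 CPM (log2 -0.06), between the 2 wild-type values. The small differences of H2afz and Brd2 turned to 0.10 and 0.06 with library totals implied by RPKM. Among the 4 BET proteins, 24 members of the H2A.Z exchange complexes and 31 Polycomb subunits, 0 were called, and the medians were -0.07, -0.10 and -0.10. With the implied totals these medians became 0.06, 0.02 and 0.03. Without wild-type replicate 1 they were 0.02, -0.08 and -0.10, and without replicate 2 they were -0.12, -0.16 and -0.11. The mean of the BET members was 0.11. Within the Polycomb list 0 members lay above and 2 below wild type at an unadjusted p under 0.05, and DESeq2 called 0 members of any of these lists.

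Bivalent genes, whose promoters carry both activating and Polycomb marks in ES cells, stood higher in the K3R3 library than in either wild-type library. Of 1671 bivalent genes tested, 175 rose (10.5%) and 9 fell. Of 10984 active genes, 92 rose (0.838%) and 52 fell. DESeq2 called 22 bivalent and 10 active genes higher, and with library totals implied by RPKM the counts were 253 and 186. Random gene sets matched to the bivalent genes on expression held 58.2 risen genes on average. The median bivalent gene was 0.65 log2 units above wild type (1.57-fold, interquartile range 0.15 to 1.24), and 81.6% of bivalent genes lay above 0. The median against each wild-type replicate alone was 0.69 and 0.63, whereas wild-type replicate 2 differed from replicate 1 by 0.05. The active median was -0.04. With the implied totals the median of all genes moved up by 0.12, and the difference between bivalent and active genes changed from 0.69 to 0.66.

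The difference between bivalent and active genes depended on expression. It was 0.65 at a mean CPM of 0.5 to 2, 0.53 at 2 to 10, 0.28 at 10 to 100 and 0.06 at 100 or more, the last range holding 24 bivalent genes. Between the wild-type replicates the same differences were -0.06, 0.14, 0.04 and 0.13, so the value above 100 CPM lay within the replicate spread. Active genes showed a slope of their own, with medians of 0.40, 0.15, -0.05 and -0.13 over these ranges. Once the trend of active genes on expression, length and GC content was taken off, bivalent genes remained 0.39 above active genes, against 0.03 in the wild-type pair. Fibroblast markers, listed because the ES cells had been kept on feeder cells until the last passage, also had a higher median in K3R3 (0.34), and the ribosomal RNA transcript Rn45s, a gene chosen after its values were seen, was lower (log2 -1.15).

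**Figure D1:**
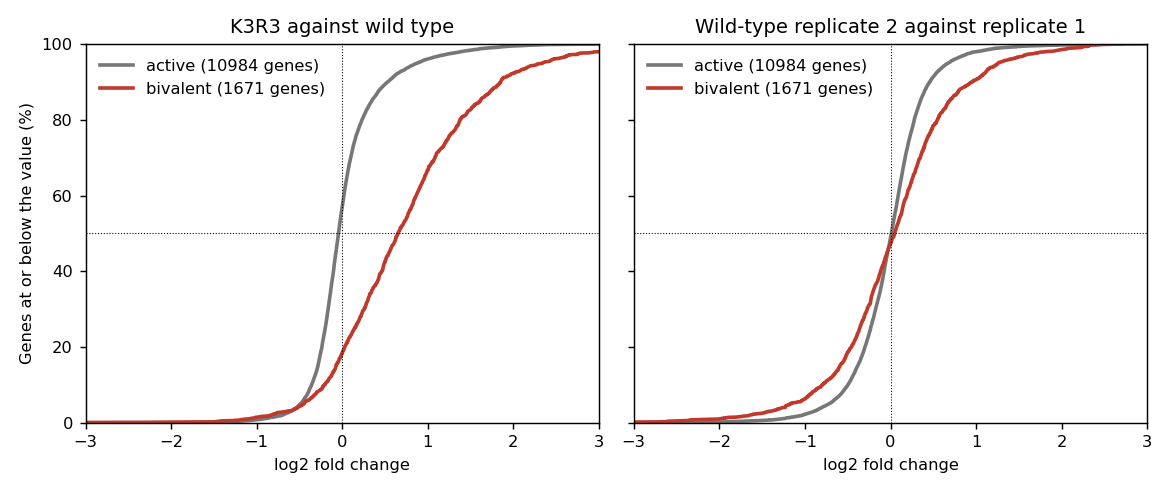
Cumulative share of genes (percent, vertical axis) at or below each log2 fold change (horizontal axis) for 1671 bivalent (red) and 10984 active (grey) genes, with K3R3 against the fitted wild type on the left and wild-type replicate 2 against replicate 1 on the right. The bivalent median lies at 0.65 on the left and at 0.05 on the right.

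Over all 13829 tested genes, 355 were called in K3R3 by edgeR's quasi-likelihood test, 280 higher and 75 lower (78.9% higher). With the implied totals 515 were called, 465 higher and 50 lower (90.3% higher). DESeq2 called 59, all among the 355, of which 33 were higher and 26 lower (55.9% higher). With a wild-type replicate put in the place of the lone library, edgeR called 9 and 0 genes, with 1187 and 152 at an unadjusted p under 0.05 against 1552 for K3R3, and DESeq2 called 27 and 1. These background counts are not on equal terms with 355, because their spread is taken between K3R3 and a wild-type library and so includes any K3R3 change (common dispersion 0.0498 and 0.0728, against 0.0325). By size alone, 290 genes lay at least 2-fold from both wild-type libraries in K3R3, 268 higher and 22 lower, against 74 and 23 for the wild-type replicates in turn. These counts are not on equal terms either, because K3R3 is then 1 of the 2 references. Those references lay farther apart (SD of the log2 difference 0.60 and 0.71, against 0.53), which makes the rule harder to meet. Of the 15311 genes in the authors' deposited table, 744 had an unadjusted p under 0.05, 562 of them higher in K3R3. Adjustment of those p-values left 43, all among the 355.

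The 12 largest rises by ratio were of genes close to silent in wild type, which a ranking by ratio favours. They reached the minimum mean CPM of 1 only through their K3R3 value, so their low wild-type level is no result. Fat3, a protocadherin gene, had 3 and 1 counts in the wild-type libraries and 91 in K3R3, a ratio of 40.1 with a counting interval of 15.1 to 150. Atp6v1c2, which encodes a subunit of the vacuolar proton pump, had 3 counts in each wild-type library and 92 in K3R3 (ratio 27, interval 11.9 to 75.5). Paqr9 had 1 and 11 counts in the wild-type libraries and 92 in K3R3 (ratio 13.5, interval 7.37 to 27.1; log2 5.32 and 2.88 against each replicate alone). Rgs7bp, a regulator of G protein signalling, had 1 and 10 against 80 (ratio 12.8, interval 6.79 to 26.7; 5.12 and 2.81), and Oprk1, the kappa opioid receptor, 2 and 12 against 77 (ratio 9.69, interval 5.44 to 18.5; 4.45 and 2.51). Tmem56 rose by 4.23 log2 units (SE 0.62; adjusted p = 3.81e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), from 0.331 ± 0.0697 to 6.26 CPM. Gabra5, a GABA receptor subunit, rose by 3.79, and Trpa1, a cation channel of sensory neurons, by 3.53. 2010300C02Rik, Ahrr (repressor of the aryl hydrocarbon receptor), Rad21l (a meiotic cohesin) and Thbs4 (thrombospondin 4) completed the 12, with log2 changes between 3.31 and 3.57. Of these 12 genes, 8 were classed as bivalent and 3 as active. DESeq2 kept the calls of Fat3, Atp6v1c2, Tmem56 and Trpa1 alone.

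The steepest falls were of genes with a range of functions. Cubn, the cubilin receptor of absorptive epithelia and visceral endoderm, fell from 81.0 ± 10.4 to 18.2 CPM (log2 -2.15, SE 0.27; adjusted p = 2.09e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Otx2, a transcription factor of epiblast and anterior neural tissue, fell from 19.8 ± 5.00 to 5.42 CPM (log2 -1.87). Srgn, which encodes the core protein serglycin, fell from 15.7 ± 0.550 to 3.38 CPM (log2 -2.22). Xaf1, an interferon-inducible gene, fell by 2.47 log2 units (-2.94 and -1.69 against each replicate alone). DESeq2 kept these 4 calls. It did not keep those of Cyp4f14 (-3.38), Klb (-2.45), Nostrin (-2.28), A2m (-2.19, with -2.61 and -1.53 against each replicate alone), 6330410L21Rik (-2.17), Gm15698 (-1.85) and Vax2os2 (-3.24). Vax2os2 is antisense to Vax2, and since the strand setting of the counting is not given, its reads cannot be told from those of its partner.

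**Figure D2:**
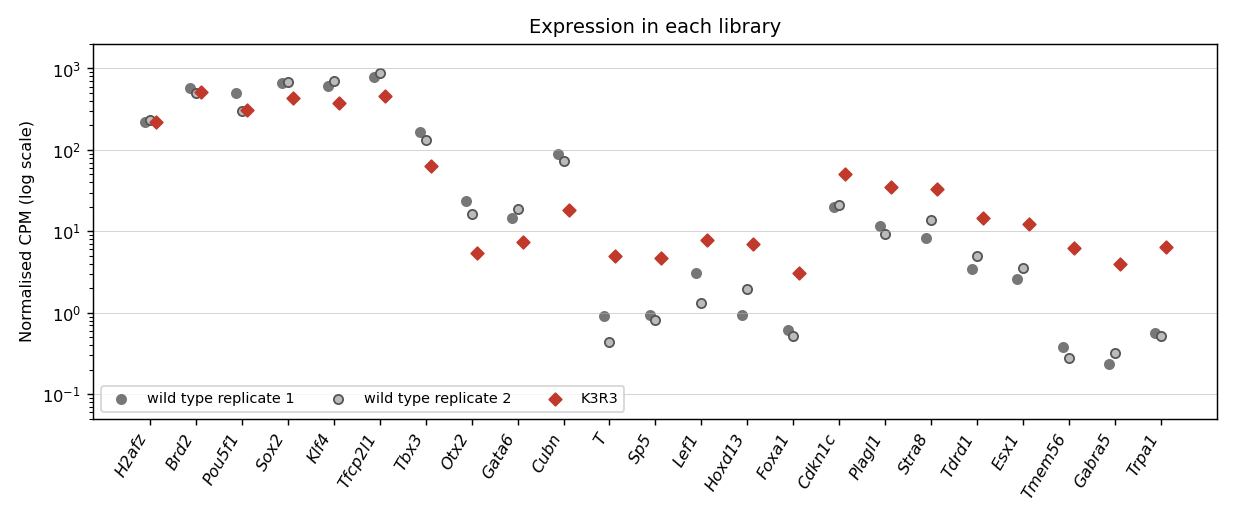
Normalised CPM on a log scale (vertical axis) of genes named in the text (horizontal axis) in wild-type replicate 1 (dark circles), wild-type replicate 2 (light circles) and K3R3 (red diamonds), 1 point per library and no error bar. H2afz, Brd2 and Pou5f1 overlap between groups or lie close, and T, Sp5, Lef1 and the genes to their right lie above both wild-type points in K3R3.

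Of 35 core and naive pluripotency genes, 0 rose and 7 fell (9 adjusted over the list alone), and 3 of the 35 lay above 0. Tbx3, a T-box factor that sustains self-renewal, fell from 149 ± 22.7 to 62.8 CPM (log2 -1.25, SE 0.22). Tfcp2l1 and Klf4, factors of the naive state, fell by 0.85 and 0.78, Tet2, which oxidises methylcytosine, by 0.83, and Fbxo15 by 0.85. Sox2 (-0.62) and Dppa5a (-0.59) also passed, Sox2 not with the implied totals or the likelihood ratio test. The change of Dppa5a was -0.23 without wild-type replicate 1. DESeq2 called 3 of the 7, Tbx3, Tfcp2l1 and Tet2. Pou5f1, which encodes Oct4, stood at 400 ± 142 against 311 CPM (log2 -0.36, with -0.69 and 0.05 against each replicate alone) and Nanog at 33.4 ± 3.24 against 37.9 CPM (0.18), neither called. Klf4, Sox2, Dppa5a, Pou5f1 and Nanog were named after their values were seen. The list median was -0.35, below all 10000 random lists, with -0.45 and -0.26 against each replicate alone, -0.23 with the implied totals and -0.10 between the wild-type replicates, itself at percentile 0.56. The fibroblast median was 0.34 in the same library, so a different mixture of cells was not separated from a lower level per cell. Of 18 primed pluripotency genes, 0 rose and 1 fell, Otx2 (2 and 1 adjusted over the list alone). Their median was 0.20 and turned to -0.02 without wild-type replicate 2.

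The medians of mesoderm genes and Wnt targets stood higher in the K3R3 library, with 13 and 16 of 19 members above 0. Of 19 mesoderm genes, 1 rose and 0 fell (7 and 0 adjusted over the list alone). T, the brachyury gene that marks the primitive streak, rose from 0.673 ± 0.326 to 4.96 CPM (log2 2.89, SE 0.60). Wnt3 (2.79), Mixl1 (2.28) and Mef2c (1.82) were not called over all genes. The list median was 1.01, at percentile 99.9, against 0.07 between the wild-type replicates. It lay inside the central 95% of random lists without the low-count filter (0.66), at a minimum mean CPM of 2 (0.57) and without wild-type replicate 2 (0.74). Of 19 Wnt targets, 3 rose and 0 fell (5 and 0 adjusted over the list alone). These were T, Sp5 (2.42) and Lef1 (1.86, with 1.36 and 2.53 against each replicate alone), transcription factors of the Wnt response. The Wnt median was 0.88, at percentile 99.7, against -0.05 between the wild-type replicates. The lists share T, 17 of the mesoderm and 12 of the Wnt genes were classed as bivalent, the fibroblast median (0.34) moved with them, and DESeq2 called 0 members of either. The random lists were matched on expression and not on class. Bivalent genes had medians of 1.05 at a mean CPM of 0.5 to 2 and 0.67 at 2 to 10. A change of these lists beyond that of their class was therefore not shown.

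Of 19 endoderm genes, 1 rose and 4 fell (1 and 7 adjusted over the list alone), and 14 were not called. The fallen genes were Cubn, Gata6 (-1.18), the factor that specifies primitive endoderm, and the basement membrane genes Col4a1 (-1.10) and Lama1 (-0.93, named after its value was seen). Foxa1, a factor of definitive endoderm, rose (2.44). The median was -0.57, below all 10000 random lists, although 13 of the 19 were classed as bivalent. It was -0.32 and -0.41 against each replicate alone and -0.27 with the implied totals, beside -0.22 between the wild-type replicates, itself at percentile 2.04. Col4a1 stood at -0.66 without wild-type replicate 1. DESeq2 kept 2 of the 4 falls, and Gata6 lost its call as well without the low-count filter, with a minimum mean CPM of 2, with the implied totals and with the likelihood ratio test.

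The medians of germline and imprinted genes stood higher in the K3R3 library, with 23 and 24 of 30 members above 0. Of 30 germline genes, 4 rose and 0 fell (9 and 2 adjusted over the list alone). Stra8, which is required for entry into meiosis, rose from 11.1 ± 4.01 to 33.6 CPM (log2 1.60, SE 0.31), Tdrd1 by 1.80 and Dmrtb1 by 2.08. Tdrd6 had 2 and 7 counts in wild type and 64 in K3R3, a ratio of 12.5 (interval 6.20 to 28.6). Their median was 0.39, at percentile 99.99, against 0.05 between the wild-type replicates, and DESeq2 kept Stra8. Of 30 imprinted genes, 3 rose and 0 fell (5 and 0 adjusted over the list alone). Plagl1 rose from 10.5 ± 1.81 to 35.5 CPM (log2 1.76), Cdkn1c, a growth-restraining cyclin-dependent kinase inhibitor, from 20.4 ± 0.933 to 51.2 CPM (1.32), and Grb10 by 0.58. The imprinted median was 0.37, above all 10000 random lists, against 0.02 between the wild-type replicates, and DESeq2 kept Plagl1 and Cdkn1c. Grb10 also lost its call with DESeq2 size factors, without the low-count filter and with the likelihood ratio test. The fibroblast median (0.34) moved with both lists. Of the tested members, 8 germline and 9 imprinted genes were classed as bivalent, among them the called Tdrd6, Dmrtb1, Tdrd1, Cdkn1c and Grb10. The random lists were not matched on class, so these medians were not separated from the rise of bivalent genes.

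**Figure D3:**
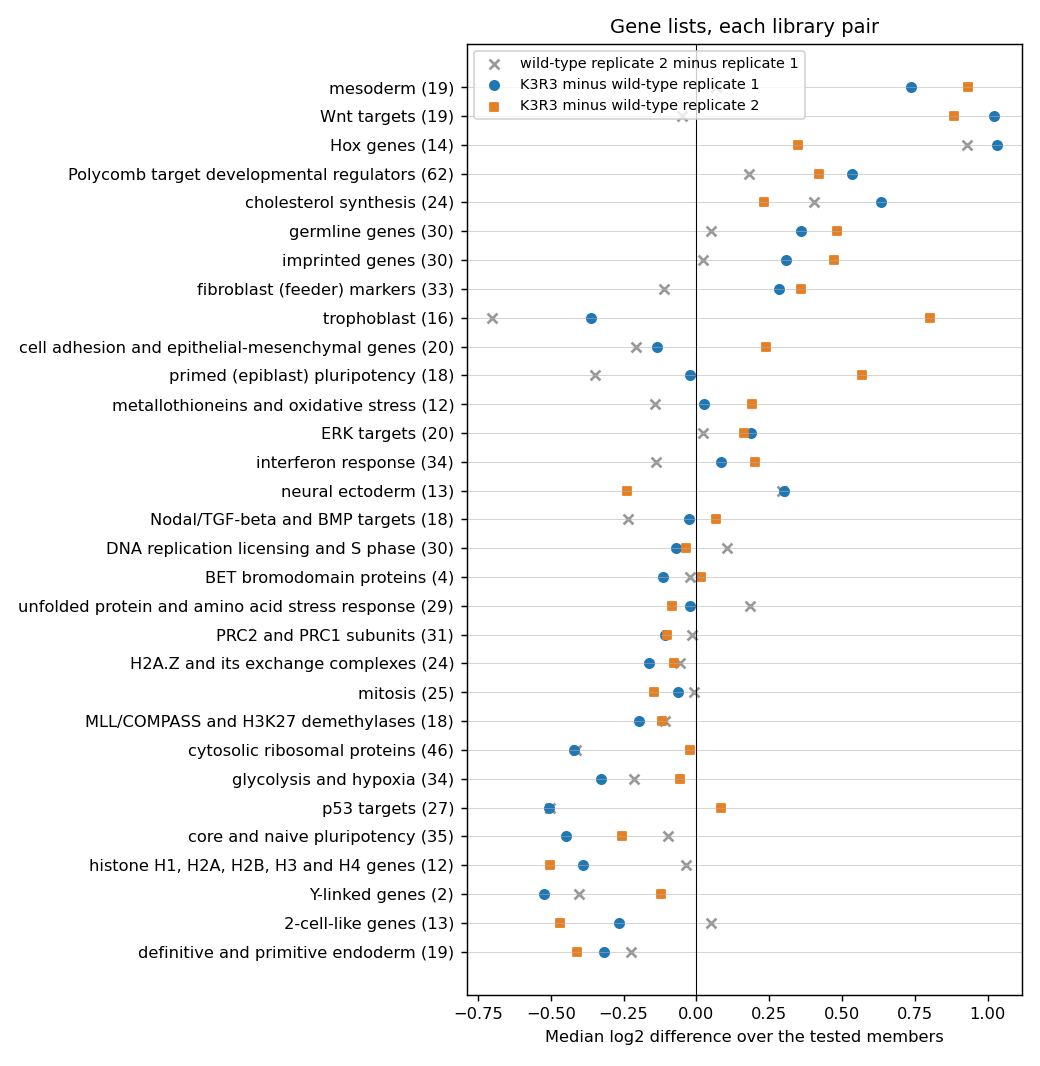
Median log2 difference (horizontal axis) over the tested members of each gene list (vertical axis, number of members in brackets) for K3R3 minus wild-type replicate 1 (circles), K3R3 minus replicate 2 (squares) and replicate 2 minus replicate 1 (crosses), each point being a median with no error bar. Mesoderm genes (0.74 and 0.93) and Wnt targets (1.02 and 0.89) lie well above 0 against both replicates, while p53 targets (-0.51 and 0.08) and trophoblast genes (-0.36 and 0.80) differ between the replicates.

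Of 62 Polycomb target regulators, 3 rose (Zic1, T and Foxa1) and 2 fell (Tbx3 and Gata6), with 11 and 3 adjusted over the list alone. Of the 62, 58 were classed as bivalent. Their median of 0.47 lay at percentile 98.5, but the wild-type replicates alone gave 0.18 at percentile 98.9. Over all bivalent genes the median was 0.65 and 10.5% rose, so this list did not exceed its class. With a minimum mean CPM of 2 the list median was -0.00061, while bivalent genes as a class still stood 0.53 above active genes. Of 14 Hox genes, 13 of them classed as bivalent, Hoxd13 rose (2.25) and 0 fell (2 and 0 adjusted over the list alone). The Hox median was 0.85 in K3R3 and 0.93 between the wild-type replicates, and it was 0.35 without wild-type replicate 1. Of 16 trophoblast genes, the homeobox gene Esx1 rose (2.01) and 0 fell (2 and 1 adjusted over the list alone), and of 13 neural genes Zic1 rose, with 4 and 1 counts in wild type and 36 in K3R3 (ratio 12.7, interval 4.96 to 41.4; 2 and 0 adjusted over the list alone). Of 33 fibroblast markers, Thy1 rose (1.77) and 0 fell (1 and 2 adjusted over the list alone), with a median above all 10000 random lists, though the mean of the members (0.23) lay inside the central 95%. The neural median was -0.02, with 0.30 and -0.24 against each replicate alone, and the trophoblast median of 0.25 was -0.36 without wild-type replicate 2. Of the single genes in this paragraph DESeq2 kept the calls of Esx1 and Tbx3 alone.

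Among lists of metabolism, stress and growth, few members were called. The median of 24 cholesterol genes was 0.41, with 0.23 without wild-type replicate 1 and 0.40 between the wild-type replicates. Pfkp and Kdm3a fell among 34 glycolysis and hypoxia genes (-0.92 and -0.80; 4 and 9 adjusted over the list alone). Parp9 rose (1.07) and Xaf1 fell among 34 interferon genes (2 and 3 adjusted over the list alone). Hist1h2bc fell among 12 histone genes (-1.75; 0 and 3 adjusted over the list alone), though its near-identical copies make its count uncertain. The other 15 lists with tested members had 0 of 319 members called by edgeR's quasi-likelihood test, with 8 higher and 15 lower at an unadjusted p under 0.05, and 0 by DESeq2. Of the genes called here DESeq2 kept Xaf1 alone. Medians were -0.27 for glycolysis and hypoxia, with -0.06 without wild-type replicate 1 and -0.21 between the wild-type replicates, 0.06 for interferon, -0.17 for MLL/COMPASS, -0.15 for mitosis, 0.07 for ERK targets, 0.11 for metallothioneins and -0.41 for 2 Y-linked genes. With 1 wild-type library left out, the interferon median ranged from 0.08 to 0.20 and that of mitosis from -0.15 to -0.06. ERK targets ranged from 0.16 to 0.19, metallothioneins from 0.03 to 0.19, MLL/COMPASS from -0.20 to -0.12 and the Y-linked genes from -0.52 to -0.12. The mean of the interferon members had the opposite sign to their median, at -0.067 (percentile 0.34 among random lists). The unfolded protein response, Nodal/BMP and S phase medians (-0.09, -0.03 and -0.06) turned to 0.03, 0.09 and 0.06 with the implied totals. Without wild-type replicate 1 they were -0.08, 0.07 and -0.04, and without replicate 2 they were -0.02, -0.02 and -0.07. Adjusted over the list alone, MLL/COMPASS had 1 higher and 1 lower and cell adhesion 2 higher and 1 lower. The p53 median of -0.28 and the ribosomal median of -0.23 stood beside -0.50 and -0.41 between the wild-type replicates, and without wild-type replicate 1 they were 0.08 and -0.02. The cell adhesion median of 0.21 was -0.13 without wild-type replicate 2.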

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

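All tests in this part were chosen after the data were seen. For 3 of them, the low-count test at 0.3, the correction for expression, length and GC content and the matched count on the X chromosome, the bound was set before the tested value was known.

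The deposited class column holds a code of -1 that its header does not explain, outside the comparison of bivalent with active genes. The 5 tested genes with this code (AI504432, Hoxb3, Sertad4, Tcam1 and Tph1) had a median log2 change of 1.58 in K3R3, against 0.37 between the wild-type replicates. One of them, AI504432, was called (log2 1.89).

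Bivalent genes stood 0.69 log2 units above active genes in K3R3 and 0.04 in the wild-type pair. A trend on expression, length or GC content as the whole cause is argued against by the 0.39 left after its removal. Carried-over feeder cells stay open, although YFP-positive cells had been sorted. The fibroblast markers had a median of 0.34, above all 10000 random lists, with 22 of 33 above 0. Of the 33, 8 were classed as bivalent, among them Thy1, the only called marker. Col1a1, Col1a2 and Col3a1 together gained 13.963 CPM against 1669 CPM for the 175 called bivalent genes. That is below a mark of 10% chosen after the data were seen. Fn1 (-0.49), Sparc (-0.57) and Vim (-0.40) had negative values without being called. So did less abundant markers such as Timp1 (-0.75), Dcn (-0.73), Anxa1 (-0.32), Acta2 (-0.28) and Tagln (-0.23). Of these, Dcn, Anxa1, Acta2 and Tagln stood in K3R3 between the wild-type replicates and above replicate 2, so they show no fall. No profile of the feeder cells was at hand. Fn1, Sparc and Vim stood at 217 CPM or more in wild type, where a small share of feeder cells would be hidden. Low counts, or genes with a 0 missing from the table, may account for part of the pattern. At a mean CPM of at least 10, where no count lay below 69, the difference was 0.2934. This was below the 0.3 set beforehand and so on the side that this explanation predicts. The margin is smaller than the 0.04 of the wild-type pair, a comparison added after the value was known. In the same range 0.2934 exceeded the wild-type 0.04 by more than 0.1, a bound chosen after both values were known. For the 443 bivalent genes of that range this comparison therefore cannot decide. Low counts and missing 0s stay open there and for genes of lower expression. With 1 K3R3 library, an effect of the lysine mutations cannot be told apart from a difference between single cultures or cell lines unrelated to the mutation.

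Weakly expressed active genes also stood higher in K3R3, with a median of 0.40 at a mean CPM of 0.5 to 2 against 0.00 between the wild-type replicates. An even background of reads over all genes in the K3R3 library would raise genes without a class code as well. Their median in the same range was 0.052, below that of the active genes, with -0.22 between the wild-type replicates. The bound for this comparison was chosen after the data were seen, and the genes were not matched on length. A spread of that size between the replicates keeps the comparison from deciding, so a background stays open. A difference between single cultures stays open here too, and no biological explanation was tested.

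Genes called higher lay on the X chromosome (GRCm38.p6, by symbol) more often than elsewhere. Of 498 X-linked genes 24 were called higher (4.82%), against 255 of 13252 autosomal genes (1.92%), and sets matched on class and expression held 7.3 on average, with a central range of 3 to 13. A larger share of bivalent or weakly expressed genes on the X is argued against by that range, and a gain in dosage of the whole chromosome by its active genes, whose median differed from the autosomal one by 0.014928. DESeq2 called 5 X-linked genes among its 33 higher calls, so the pattern rests on few genes by that test. A difference between single cultures or lines stays open, and no biological explanation was tested.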

How the results depend on the processing

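Library totals implied by RPKM and all settings of the bivalent comparison were chosen after the data were seen. The count of 355 changed genes stayed within 1.5 times under every other setting except the DESeq2 Wald test, which called 59. It has no value without a wild-type replicate, because 1 library against 1 leaves no residual degree of freedom. Of the 355 genes, which were selected for their difference from these same libraries, 277 stood at 2-fold or more without replicate 1 and 321 without replicate 2. The 290 genes at least 2-fold from both wild-type libraries became 976 at 1.5-fold and 3 at 4-fold, as the threshold moved, and 454 to 688 with 1 wild-type library left out, where a gene had 1 condition fewer to meet. The bivalent minus active difference of 0.69 was 0.74 without a low-count filter, 0.53 at a minimum mean CPM of 2, 0.66 with the implied totals, 0.39 with the trend taken off, and 0.66 to 0.72 without a wild-type replicate. Between 13 and 19 lists lay outside the central 95% of random lists over the settings, against 17 as reported, with 12 to 17 shared. The wild-type pair alone gave 13 such lists. The median of Polycomb target regulators reversed to -0.00061 at a minimum mean CPM of 2. That of p53 targets ranged from -0.51 to 0.083, and that of cell adhesion genes from -0.13 to 0.24, without a wild-type replicate. With the implied totals, which moved the median of all genes by 0.12, H2afz (0.10), Brd2 (0.065) and Brd3 (0.053) changed sign. The cause of these reversals was not tested, except that the scaling shift exceeds each of those gene values. No paired analysis was possible because the K3R3 library carries no replicate number, so the groups share fewer than 2. The pseudocount settings were not run, since the table holds counts.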

Other observations

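The genes in this part were chosen after their values were seen, apart from the Y-linked genes. Fndc3c1, an X-linked gene, had the smallest p-value of all tested genes and rose from 11.4 ± 4.93 to 62.6 CPM (log2 2.45, SE 0.28; adjusted p = 8.58e-14 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Lpl, lipoprotein lipase, rose from 5.42 ± 2.88 to 29.7 CPM (log2 2.45), and Cd24a, a cell surface glycoprotein gene, from 115 ± 14.2 to 232 CPM (1.01). Both are classed as bivalent, and DESeq2 kept all 3 calls. Other X-linked genes that rose were Nrk (2.33), Lonrf3 (1.46), Apln (1.90), which encodes the ligand apelin, the glypican gene Gpc3 (0.81) and the neural adhesion gene L1cam (1.52). DESeq2 kept Nrk and Lonrf3 but not Apln, Gpc3 or L1cam, and L1cam stood at 2.26 without wild-type replicate 1 and 1.00 without replicate 2. Morc1, a germline gene, fell from 74.9 ± 13.2 to 24.3 CPM (log2 -1.62). Dnmt3l, a cofactor of de novo DNA methylation, fell by 0.94 log2 units, but its wild-type level of 141 ± 95.5 CPM spans the 73.6 CPM of K3R3, its change was -0.004 without wild-type replicate 1, and DESeq2 did not call it.

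Rn45s, a ribosomal RNA transcript, took 0.048%, 0.0349% and 0.0202% of the counts in wild-type replicates 1 and 2 and K3R3. The 12 histone genes tested had a median of -0.37 in K3R3 and -0.03 between the wild-type replicates. Many but not all histone transcripts lack a poly(A) tail, and the 12 were not separated on this. The histone median was -0.19 without the low-count filter and -0.20 at a minimum mean CPM of 2, the latter inside the central 95% of random lists. The 13 tested genes of the 2-cell-like state had a median of -0.48, below all 10000 random lists, with -0.27 without wild-type replicate 2, 0.05 between the wild-type replicates and 0 members called or at an unadjusted p under 0.05 by edgeR's quasi-likelihood test, and 0 called by DESeq2. Several of them belong to families of near-identical copies and are uncertain.

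The labels name V6.5 ES cells, described as male, for growth and KH2 ES cells for the transgenic lines, and do not say how the 2 relate. Y-linked transcripts were scarce in all 3 libraries. Ddx3y had 35, 59 and 48 counts in wild-type replicates 1 and 2 and K3R3, and its X-linked homologue Ddx3x had 42836, 50004 and 46633. Eif2s3y had 62, 29 and 33 counts, Kdm5d 6, 6 and 15, and Uty 12, 14 and 8. Neither of the 2 tested Y-linked genes was called.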
